A study of Homo sapiens with 2 samples.

How the data were processed

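Total RNA from mock and RHCG-transfected KYSE30 cells was depleted of ribosomal RNA with RiboMinus and made into barcoded libraries with the Ion Total RNA-Seq kit for Ion Torrent sequencing. There was 1 library per group, 2 libraries in all, and the labels gave the groups. The submitters' processing notes name the genome build hg19 and bedtools 2.25.0; the aligner and the counting method are not given in the sources used here.

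The authors deposited 1 table per library, with a header of RPKM, but its values were log2 values of RPKM with no pseudocount. No value was below 0. A gene listed at 0 may have had 1 RPKM or less, no reads, or not been counted: generally expressed genes such as HSPH1, GLUL and RN7SK were at 0 in both libraries, and the files do not tell these cases apart. The scale was checked on single-exon small RNA genes: the unlogged value times the transcript length fell in piles on whole multiples of 1 constant per library, 52.8 in the mock and 45.3 in the RHCG library. These constants correspond to about 18900000 reads and about 22100000 reads. Of the small RNA values under 20 reads, 24.0% (44 of 183) and 36.6% (64 of 175) lay within 0.002 reads of a whole number, and counts could not be recovered. Whether reads were split between genes or the authors' transcript lengths differed from those used here was not tested. The design fixed before the data were examined was written for counts, and its fallback for RPKM was used.

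Each table had 40448 rows, among them 112 with a copy suffix, which were summed to 40392 Entrez genes. No mitochondrially encoded gene was among them, and these genes were not analysed here. Genes listed at 0 were set to 1 RPKM, a choice made after the unit was known. The ratio was log2((RHCG + 1)/(mock + 1)) in RPKM for the 12857 genes with a mean of at least 1 RPKM, with the deposited scaling kept. A log2 ratio of 1 or more was called higher and of −1 or less lower, with no interval and no p-value. Ratios of genes listed at 0 in 1 library depend on that floor, and their RPKM are given in place of a ratio.

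Before the data were examined, 35 gene lists were fixed (23 of pathways, 7 of RNA composition and 5 of other cell types). Each list median was set against 10000 random lists of the same size, drawn in 20 bins of mean expression, as a description of these 2 libraries, and genes in a list are not independent. Named genes were RHCG and MMP1, the 12 highest and 12 lowest by log2 ratio (small RNA, antisense and uncharacterised symbols left out), and up to 4 called members of each list or, in a list with none, the 2 most abundant; 1 gene that the rule names is not reported. Approximate read numbers were RPKM times GENCODE exonic length times the recovered depth, for 97.8% of tested genes. They gave approximate 95% exact (Clopper-Pearson) counting intervals of ratios, which cover counting error only.

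Chromosome positions came from the RefSeq annotation of GRCh38, so no coordinates are given. Shifts along chromosomes were measured over 9207 protein-coding genes with a mean of at least 3 RPKM, histone genes left out, with 1000 shuffles of the genes. Segments were stretches of a set least length, scored by their summed ratios, clipped at 1 from the median, over the square root of their length. Their score had to exceed the highest found in a separate and smaller set of shuffled orders.

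Alternatives were a pseudocount of 0.1 RPKM, no filter, the row with the highest total for each gene, median-of-ratios scaling, trimmed mean scaling without structural RNA, histone and ribosomal protein genes, and a ratio of 1.5. Added after the data were seen were the trimmed mean over all genes, both uses of the counting interval, genes listed at 0 set to 0 RPKM, a mean of at least 5 RPKM, removal of a lowess trend with GC content and length, and removal of the median shift of 51 neighbouring genes. Histone genes were kept among these neighbours. The rule was tested on simulated data with counting error only. Of 50 genes per simulated fold it recovered 86% at 2.5-fold, 98% at 4-fold, 66% at 0.4-fold and 80% at 0.25-fold, and 12 (0.0970%) of the genes with no simulated change were called. The floor limits what can be recovered among lower genes of low abundance. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with a fixed random seed of 21.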

Results

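KYSE30 is an established cell line from an esophageal squamous cell carcinoma. RNA sequencing of total RNA was carried out on 2 libraries. The mock library came from cells stably transfected with the pIRES2-EGFP vector, and the RHCG library from cells stably transfected with a vector that expresses human RHCG. The labels do not say whether both vectors share a backbone. RHCG is an ammonia and ammonium transporter of the Rhesus glycoprotein family that normal esophageal epithelium expresses. With 1 library per group there is no replicate spread, no test between the groups was made, and every difference below compares these 2 libraries. The depth scaling of the deposited values corresponded to about 18900000 reads in the mock library and about 22100000 reads in the RHCG library. A transcript of 1 kb at 1 RPKM (reads per kilobase, scaled to depth) thus rested on about 18.9 and 22.1 reads. Values above 1 RPKM were listed for 12494 genes in the mock library and for 12229 in the RHCG library, 11866 of them in both.

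The transfected gene was found where the labels place it. RHCG (Entrez gene 51458, chromosome 15) was listed at 0 in the mock library and at 413 RPKM in the RHCG library. It ranked 63 among the 10968 protein-coding genes listed there. The table holds 1 value per gene, so reads from the vector and from the chromosomal gene were counted together.

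The comparison asks how the transcriptome of KYSE30 cells differed when RHCG was expressed. The median log2 ratios of RHCG over mock of the S phase, histone, interferon-stimulated, heat shock and cholesterol synthesis lists lay below the range of random lists, and the median of the unfolded protein and amino acid stress genes lay above. In the S phase list all 21 genes lay below 0, with a median log2 ratio of −1.43, and 13 of them were lower by the 2-fold rule. In the stress list 11 of 24 genes were higher and 1 was lower, with a median of 0.91. Among 12857 genes with a mean of at least 1 RPKM, 352 (2.74%) had a log2 ratio of RHCG over mock of 1 or more and are called higher, and 424 (3.30%) had one of −1 or less and are called lower. Between the libraries 77.2% of all genes lay within 1.5-fold, and the SD of log2 ratios was 0.54.

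**Figure D1:**
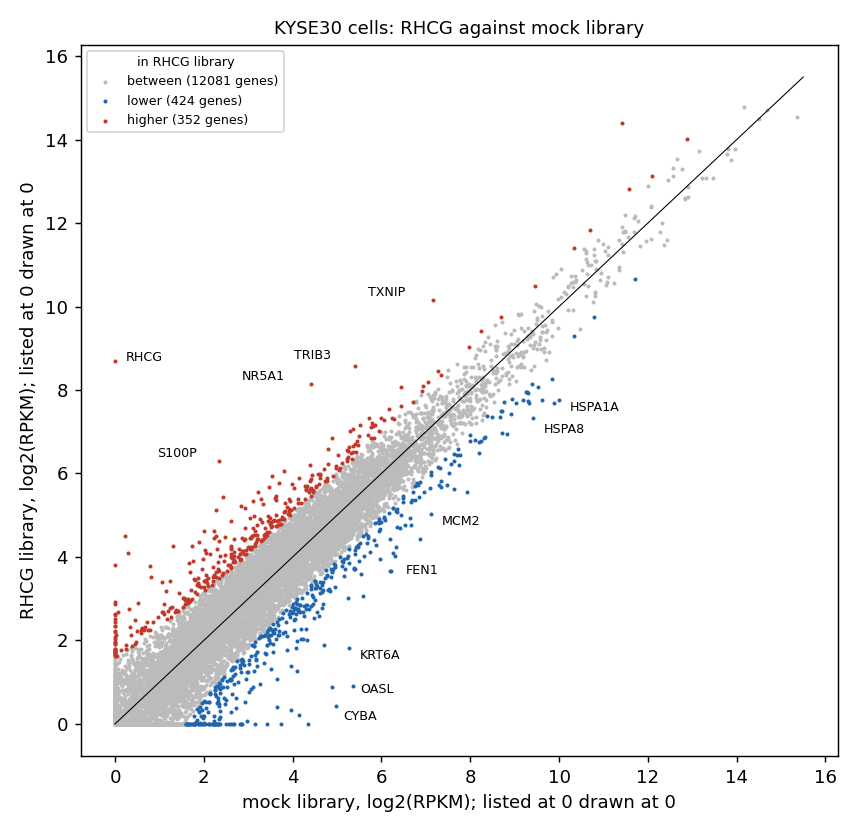
Each point is 1 of the 12857 genes, with log2(RPKM) in the mock library on the x axis and in the RHCG library on the y axis; genes listed at 0 are drawn at 0 and the line marks equal values. Red points are the 352 genes called higher and blue points the 424 called lower; RHCG lies at 0 on the x axis and 8.69 on the y axis.

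Apart from RHCG, S100P, a small calcium-binding protein, had the highest log2 ratio with 1 RPKM added to each value. It was at 5.04 RPKM in the mock library and 79.3 in the RHCG library, a log2 ratio of 3.73. NR5A1, the nuclear receptor steroidogenic factor, was at 21.2 and 283 RPKM (log2 ratio 3.68). TRIB3, a pseudokinase induced by amino acid shortage, was at 42.4 and 379 RPKM (3.13). TXNIP, the thioredoxin-interacting protein that responds to glucose, was at 142 and 1141 RPKM, an 8.02-fold difference. The others of the 12 highest were ITGBL1 (3.45), TMEM45B (3.03), the sulfatase gene ARSI (2.81), the homeobox gene HOXD1 (2.63), the imprinted non-coding RNA HYMAI (2.54), METTL24 (2.45) and PRR18, which was listed at 0 in the mock library and at 14.1 RPKM in the RHCG library. The order depends on the value added: the plain ratio of ITGBL1 was 19.5-fold against 15.7-fold for S100P, and PRR18 had a log2 ratio of 3.91 with genes listed at 0 set to 0 RPKM.

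At the other end stood OASL, an interferon-induced gene, at 41.0 RPKM in the mock library and 1.88 in the RHCG library (log2 ratio −3.87). CYBA, which encodes the p22phox subunit of NADPH oxidase, was at 31.7 and 1.35 RPKM (−3.80), and the secreted metalloproteinase gene ADAMTS1 at 29.6 and 1.85 RPKM (−3.42). KRT6A, a keratin of activated squamous epithelium whose sequence is close to that of other keratin 6 genes, was at 38.8 and 3.51 RPKM (−3.14). The histone variant gene MACROH2A2 had a ratio of −2.87, MYEOV −3.11, CSRP2 −2.54, the Notch-modifying glycosyltransferase gene LFNG −2.53, and ETFB, a subunit of the electron transfer flavoprotein, −2.48. IFI44 (13.4 RPKM in the mock library), CNTN1 (10.7 RPKM) and RBM14-RBM4 (20.2 RPKM) were listed at 0 in the RHCG library. RBM14-RBM4 is a readthrough gene that shares its exons with its neighbours.

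Both cell cycle lists had medians below 0, and 13 of 21 S phase genes but 2 of 25 G2 and M phase genes were lower by the 2-fold rule. FEN1, a nuclease of lagging-strand synthesis, was at 79.1 RPKM in the mock library and 16.2 in the RHCG library. The replicative helicase genes MCM5 and MCM2 were at 76.6 and 17.2 RPKM and at 138 and 32.4 RPKM, and TYMS, thymidylate synthase, had a log2 ratio of −2.02. The S phase median of −1.43 had an approximate 95% counting interval of −1.48 to −1.37, and 95% of the medians of random lists matched on expression lay between −0.25 and 0.26. Of 25 G2 and M phase genes, 24 lay below 0, the lower ones were KIF20A (41.5 and 13.1 RPKM) and CDK1 (23.1 and 10.2 RPKM), and the median was −0.42. All 46 measured replication-dependent histone genes lay below 0 and 20 were lower, with a median of −0.95. This median was −0.38 with the shift of neighbouring genes removed. Histone genes were among those neighbours, so the removal can take out part of their own shift. H1-1 had a log2 ratio of −2.40, H3C12 −2.38, H2AC12 −2.34 and H2AC4 −1.98. Histone genes have near-identical copies that share reads.

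Of 21 interferon-stimulated genes, 8 were lower and 0 higher, with a median of −0.75, which was −1.20 with a mean of at least 5 RPKM. Besides OASL and IFI44, OAS1, which senses double-stranded RNA, was at 16.8 RPKM in the mock library and 3.51 in the RHCG library, and IFIT3 at 9.68 and 1.93 RPKM. Of 14 antigen presentation genes, 0 passed 2-fold in either direction, 5 lay above 0 and 9 below. Their median was −0.08, inside the random range of −0.29 to 0.27. The most abundant, HLA-C and B2M, were at 209 and 242 RPKM and at 143 and 181 RPKM.

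Of 15 heat shock genes, 5 were lower and the median was −0.79. HSPA8, the constitutive Hsp70 chaperone, was at 685 RPKM in the mock library and 160 in the RHCG library. HSP90AA1 was at 457 and 123 RPKM, and the near-identical pair HSPA1A and HSPA1B had log2 ratios of −2.24 and −2.20. Of 23 cholesterol synthesis genes, 5 were lower and the median was −0.55; HMGCS1 had a ratio of −1.42, MVK −1.39, FDFT1 −1.16 and MSMO1 −1.15. Of 27 hypoxia and glycolysis genes, 7 were lower and the median was −0.40. It was −0.61 with a pseudocount of 0.1 RPKM, −0.83 with a mean of at least 5 RPKM and −0.64 with the shift of neighbouring genes removed. LDHA, lactate dehydrogenase A, was at 296 and 107 RPKM, ENO1 at 734 and 270 RPKM, P4HA2 at 42.3 and 16.7 RPKM, and BNIP3 at 37.5 and 15.6 RPKM. Cytosolic ribosomal protein genes had a median of −0.36, with 5 of 75 lower (RPL27A −1.15, RPS13 −1.07, RPS14 −1.04 and RPLP0 −1.03 among them). House-keeping reference genes had a median of −0.28, and 3 of 27 were lower, TUBA1B (−1.58), PGK1 (−1.17) and RPLP0. Genes chosen as a stable reference thus also lay below their random range, −0.24 to 0.22, under every setting. The ribosomal protein median likewise lay below its range of −0.18 to 0.12.

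The median of the unfolded protein and amino acid stress genes, 0.91, lay above the central 95% of random list medians, −0.26 to 0.23; 19 of the 24 genes lay above 0 and 5 below. SESN2, a sestrin that restrains growth signalling under amino acid shortage, was at 15.8 RPKM in the mock library and 54.0 in the RHCG library. ASNS, asparagine synthetase, was at 52.5 and 161 RPKM, and SLC7A11, the cystine transporter, at 4.60 and 13.6 RPKM. Among 20 p53 target genes, 3 were higher and 1 lower, with a median of 0.38 (0.65 with a mean of at least 5 RPKM): the cytokine gene GDF15 (1.93), SESN2 (1.71), the death receptor gene TNFRSF10B (1.34) and DDB2 (−1.20). YAP target genes had a median of 0.60 with 1 of 16 higher, ANKRD1, at 8.67 and 40.3 RPKM. Immediate early and AP-1 genes had a median of 0.37 with 1 of 21 higher, FOSL1, at 39.5 and 89.6 RPKM. SESN2, ASNS, SLC7A11 and FOSL1 each stand in more than 1 list.

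**Figure D2:**
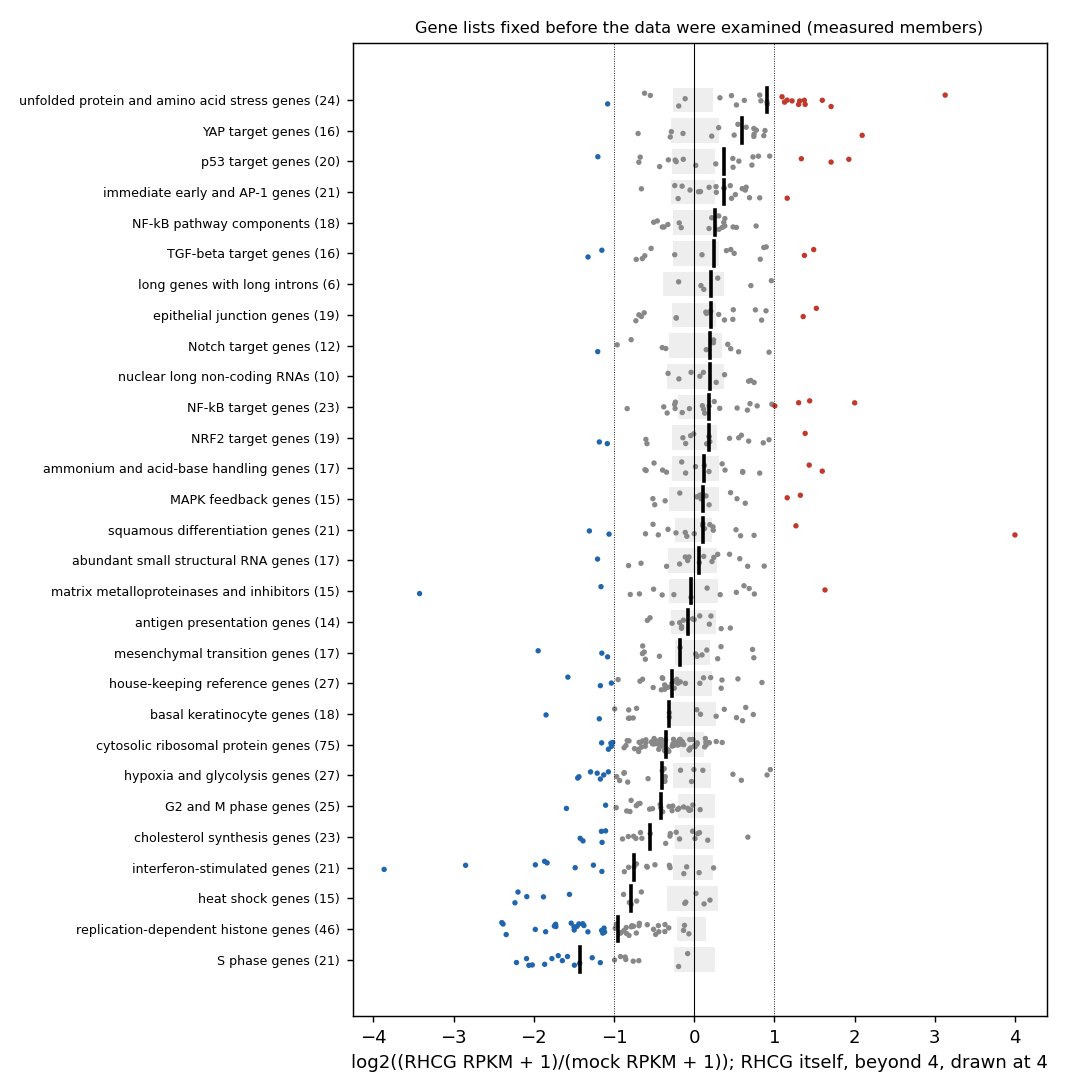
Each row is a gene list fixed before the data were examined, with its number of measured genes in brackets, and each point a gene's log2 ratio of RHCG over mock, red for higher, blue for lower and grey for neither. Black bars are list medians and grey boxes the central 95% of medians of random lists matched on expression; the stress genes have the highest median, 0.91, and the S phase genes the lowest, −1.43.

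The study named NF-kB signalling and MMP1 as its subject, so these were looked at whatever their values, and they are not independent evidence. MMP1, an interstitial collagenase, was listed at 0 in both libraries, as were MMP3, MMP7, MMP9, MMP12 and MMP13, so no ratio could be given. A 0 in both libraries sets no bound on expression, since HSPH1 and GLUL, which cells generally express, were also listed at 0 in both. Among 15 measured matrix metalloproteinases and inhibitors, ADAMTS1 and MMP2 (−1.16) were lower and the inhibitor gene TIMP3 (1.63) was higher, with a median of −0.04 that was 0.07 with a GC and length trend removed. Of 23 NF-kB target genes, 4 were higher and 0 lower: PTGS2, the inducible cyclooxygenase, at 9.70 RPKM in the mock library and 41.8 in the RHCG library, IL1A at 3.44 and 11.1 RPKM, PLAU at 37.5 and 94.0 RPKM, and BIRC2 at 5.77 and 12.6 RPKM. Their median of 0.19 lay inside the range of random lists, −0.20 to 0.20. With genes listed at 0 set to 0 RPKM it was 0.54, above its range of −0.29 to 0.27. With a GC and length trend removed it was 0.25, above −0.19 to 0.21. With the shift of neighbouring genes removed it was 0.17, just above −0.22 to 0.16. With a mean of at least 5 RPKM it was 0.19, inside −0.24 to 0.33. Of the 33 genes on this list, 10 were listed at 0 in both libraries, IL6 and TNF among them. None of the 18 NF-kB pathway components passed 2-fold in either direction, and their median was 0.26, or 0.06 with the shift of neighbouring genes removed; IRAK1 was at 266 and 372 RPKM and TNFRSF1A at 60.7 and 79.4 RPKM.

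Epithelial identity genes went both ways. Of 21 squamous differentiation genes, RHCG itself and GRHL1 (1.27) were higher and KRT13, a keratin of the upper esophageal layers, was lower, at 407 RPKM in the mock library and 164 in the RHCG library, as was ECM1 (−1.06). Basal keratinocyte genes had a median of −0.31 with 2 of 18 lower, KRT15 (−1.85) and SOX2 (−1.18), and this median lay below the random range of −0.29 to 0.27. It was −0.21, inside its random range, once a trend with GC content and transcript length was removed. Of 19 epithelial junction genes, OCLN (1.52) and CLDN1 (1.36) were higher and 0 were lower. The junction median was 0.21, inside its random range of −0.27 to 0.28, with 13 genes above 0 and 6 below. Of 17 mesenchymal transition genes, VIM (−1.95), TGFBI (−1.15) and SNAI2 (−1.08) were lower and 0 were higher. Their median was −0.18, inside −0.24 to 0.20, with 8 genes above 0 and 9 below. It lay below its range with genes listed at 0 set to 0 RPKM (−0.43) and with a mean of at least 5 RPKM (−0.63). TGF-beta target genes were split, with COL4A2 (1.49) and COL4A1 (1.37) higher and ID3 (−1.32) and TGFBI lower among 16. Their median was 0.25, inside −0.27 to 0.30, and that of the squamous differentiation genes 0.11, inside −0.24 to 0.22. The 17 measured genes for ammonium and acid-base handling, among them ASNS, had a median of 0.13, inside the random range of −0.27 to 0.31, and of 0.06 with a GC and length trend removed.

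Other lists had medians inside the random range: MAPK feedback genes 0.11 (DUSP5, at 1.32, and FOSL1 higher), NRF2 target genes 0.18 (SLC7A11 higher, CBR1, at −1.18, and PGD, at −1.08, lower), Notch target genes 0.19 (DLL1, at −1.20, lower), abundant small structural RNA genes 0.06 (TERC, at −1.21, lower), nuclear long non-coding RNAs 0.19 and long genes with long introns 0.21. With the shift of neighbouring genes removed, the NRF2 median was 0.38, above its random range of −0.22 to 0.23, and the Notch and structural RNA medians were −0.08 and −0.09. The median of MAPK feedback genes was 0.18 with a GC and length trend removed. That of long genes was 0.08 with the neighbour shift removed. With a mean of at least 5 RPKM it was 0.71, at the upper end of its random range of −0.63 to 0.71. Only 6 of the 18 long genes were measured even without that filter. Few markers of other cell types were measured. Of 12 fibroblast markers 3 were measured (FBLN1 at 6.52 and 5.47 RPKM, COL1A1 at 1.19 and 1.44 RPKM), of 10 endothelial markers 1 (EGFL7, 16.7 and 17.2 RPKM), of 13 leukocyte markers 1 (CD68, 15.4 and 8.89 RPKM) and of 8 erythroid markers 0. Of 12 simple columnar epithelium markers 3 were measured, of which KRT19 was lower, at 1766 and 855 RPKM.

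Log2 ratios also ran together along chromosomes. Over 9207 protein-coding genes, the 137 genes of chromosome 13 had a median log2 ratio of 0.57 and 89.1% of them lay above 0, with 21 called higher and 0 lower. The medians of chromosomes 2 (0.30), 18 (0.21) and 7 (0.21) also lay above, and those of chromosomes 12 (−0.22), 19 (−0.18) and 5 (−0.10) below, any of 1000 shuffles of the genes. With a GC and length trend removed, chromosome 18 was at 0.14 and 31 shuffles were as far, and chromosome 19 was at −0.07 and still below all shuffles, while chromosomes 11 (0.13) and 16 (0.14) lay above all shuffles. Shifts also differed within chromosomes: chromosome 5 held a stretch of 149 genes with a median of 0.41 and one of 250 genes at −0.32, chromosome 7 one of 260 genes at 0.40 and one of 90 at −0.32, chromosome 11 one of 137 genes at −0.45 and one of 140 at 0.47, and chromosome 12 one of 61 genes at 0.44 and one of 386 at −0.34. The raised stretch of chromosome 12 was not found with a GC and length trend removed, nor in a search over every other gene. COL4A1 and COL4A2 are neighbours on chromosome 13. With the median shift of 51 neighbouring genes removed, 246 genes were higher and 387 lower, and these held 186 (52.8%) of the 352 and 299 (70.5%) of the 424 genes. Named genes that then no longer passed 2-fold included IL1A (0.88), BIRC2 (0.43), FOSL1 (0.97), GRHL1 (0.88), COL4A1 (0.79), COL4A2 (0.91), TGFBI (−0.74), P4HA2 (−0.97), ECM1 (−0.97), KRT19 (−0.90), RPL27A (−0.68), RPS13 (−0.73), RPS14 (−0.75) and RPLP0 (−0.66). BIRC2, at 1.01, was just under 1 with the other scalings and 0.88 with the GC and length trend removed, which also put ECM1 (−1.06) at −0.96, RPS13 (−1.07) at −0.81, RPLP0 (−1.03) at −0.99 and KRT19 (−1.05) at −0.90.

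**Figure D3:**
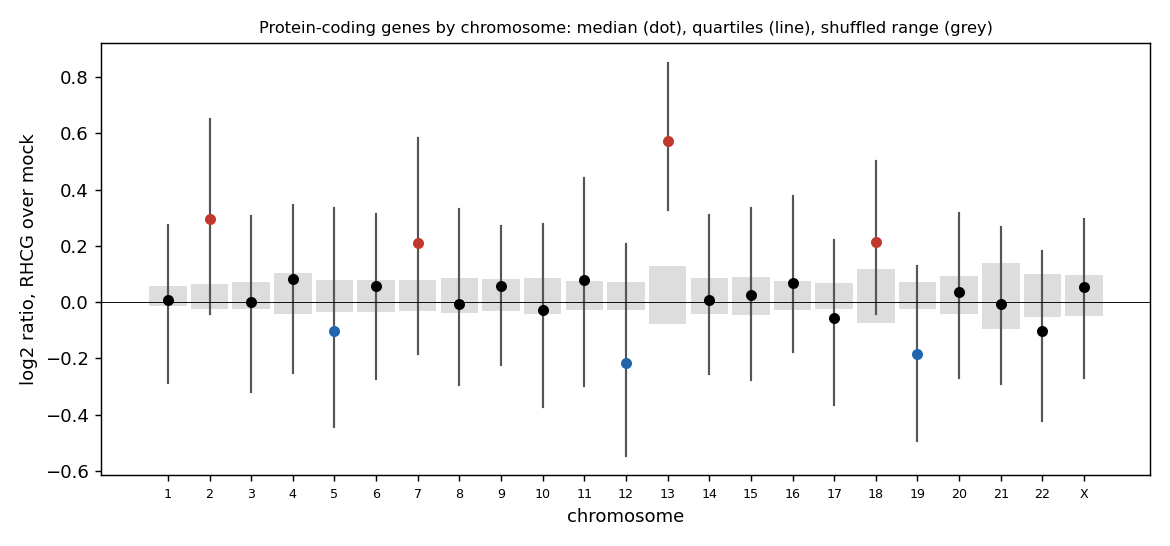
For each chromosome, the dot is the median log2 ratio of RHCG over mock of its protein-coding genes, the line runs from the lower to the upper quartile and the grey box is the central 95% of medians under shuffled gene positions. Chromosomes 2, 7, 13 and 18, in red, lay above and chromosomes 5, 12 and 19, in blue, below all 1000 shuffles, which for chromosome 18 did not hold with a GC and length trend removed; chromosome 13 has the highest median, 0.57.

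Approximate read numbers gave a counting interval of the ratio that excluded 1 for 331 of the higher and 397 of the lower genes, but such intervals cover counting error only. They hold no difference between cultures, clones or library preparations, which 1 library per group leaves inside every value.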

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

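The settings with genes listed at 0 set to 0 RPKM, a mean of at least 5 RPKM, the GC and length trend removed, the neighbour shift removed, the trimmed mean over all genes and the counting intervals were chosen after the data were seen. No paired analysis was possible because there was 1 library per group, and no library could be left out. The 352 higher and 424 lower genes became 533 and 673 with a pseudocount of 0.1 RPKM, 1447 and 1481 with a ratio of 1.5, and 686 and 1004 with genes listed at 0 set to 0 RPKM. Each of these settings loosens the rule by construction, and each kept all 352 and 424 genes. The RHCG ratio on the log2 scale, 7.69 against a floor of 1 RPKM, became 8.55 with a pseudocount of 0.1 RPKM and 8.69 with the floor at 0 RPKM, again by construction. The other settings gave 246 to 366 higher and 296 to 434 lower genes, within 1.5 times of the reported counts. Among list medians and named genes, 946 values under the alternatives moved by no more than their approximate counting error and 156 by more, and no called value turned its sign. Of the list medians, 10 lay below and 4 above the random range; the settings gave 9 to 11 below and 4 to 6 above. The NF-kB target genes moved above it with genes listed at 0 set to 0 RPKM, with the GC and length trend removed and with the neighbour shift removed. The NRF2 target genes moved above it with the neighbour shift removed (0.38). The mesenchymal transition genes moved below it with genes listed at 0 set to 0 RPKM (−0.43) and with a mean of at least 5 RPKM (−0.63). The median of the replication-dependent histone genes moved from −0.95 to −0.38 with the neighbour shift removed. The neighbouring genes in that setting included histone genes, so the removal can take out part of the shift of clustered histone genes themselves. H1-1, H3C12, H2AC12 and H2AC4 lie on chromosome 6, where protein-coding genes with histone genes left out had a median of 0.06. The histone median was not computed against neighbours without histone genes, so −0.38 does not show a shift shared with other genes. The other scalings moved all ratios by less than 0.01. Leaving the filter out moved nothing, since all genes above the floor pass it. The planned settings that need counts (a prior count of 3, a summed count of at least 100, a thinned library) were not run, and MMP1 has no ratio under any setting. Genes listed at 0 in both libraries, MMP1 among them, cannot be assessed here, whatever the depth.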

Other observations

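The genes in this paragraph and the next were picked after their values were seen. ARRDC4, an arrestin family gene controlled by the same glucose-sensing factor as TXNIP, was at 4.07 RPKM in the mock library and 18.0 in the RHCG library. PLAGL1, which shares the imprinted locus of HYMAI, was at 5.09 and 20.7 RPKM. CDK19, beside METTL24 on chromosome 6, was at 7.13 and 37.3 RPKM. DDIT4, a stress-induced inhibitor of growth signalling, was at 304 and 682 RPKM. Among keratins of activated epithelium, KRT16 was at 4.40 and 16.9 RPKM and KRT17 at 24.5 and 14.5 RPKM, while KRT6A was lower.

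Small RNA classes were not compared with each other by a test. Of 229 small nucleolar RNA genes, 13 were higher and 4 lower, with a median log2 ratio of 0.26. Of 246 microRNA genes, 22 were higher and 16 lower, with a median of 0.04. Of 23 small nuclear RNA genes, 0 were higher and 11 lower, with a median of −0.90. Of the 36 genes on the abundant small structural RNA list, 19 were listed at 0 in both libraries. Of 19 genes of the SNAR family, small RNAs bound by a double-stranded RNA binding protein, 11 were lower and the median was −1.25, and their near-identical copies share reads.

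Of the tests below, only the one on left-out genes of chromosome segments was set out before its result was seen; the others were chosen after. The median of the S phase genes lay below random lists. A scaling factor moves all genes alike and so could not set these genes apart, whatever the values. The S phase median lay −1.42 from the median of all genes. With the GC and length trend removed the S phase median was −1.36, which argues against GC content and transcript length. The S phase median minus the G2 and M phase median was −1.01, outside the −0.41 to 0.43 of shuffled memberships. This argues against a smaller share of cycling cells alone only if such a share lowers both lists alike, which was not tested. A smaller share of cycling cells that lowers the lists unequally stays possible. A lower expression of replication genes in RHCG cells describes these values without explaining them. An unequal culture state unrelated to RHCG, such as density, cannot be told apart from an effect of RHCG with 1 library per group.

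Log2 ratios shifted together along chromosome arms. The correlation of neighbouring genes, across genes that are not independent replicates, was 0.20, and 0 of 1000 shuffles reached it (highest 0.04), and with the GC and length trend removed it was 0.18, again above all shuffles. Segments found from every other gene were checked on the genes left out: in 10 of 10 segments (100%) these shifted the same way, with medians of 0.26 to 0.58 in size, and 10 other draws of the threshold gave 8 to 11 segments, again all the same way. This is consistent with a copy-number difference between both transfected populations, which may have arisen on selection or cloning, but regulation of whole regions would also give it and DNA was not examined here. Raised segments held 14.1% of these genes and 46.4% of their higher calls, a share inflated because the same ratios defined the segments.

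The median of the 24 unfolded protein and amino acid stress genes lay above random lists, with 11 of them higher. With the neighbour shift removed the list median was 0.80, which argues against copy-number shifts shared with neighbouring genes as the whole account. That removal leaves copy-number changes of single genes in place, so these were not tested. The GC and length trend does not account for the raised median, since the list median was 0.95 with that trend removed. Whether stress in the endoplasmic reticulum alone may lie behind the raised median stays open. The 8 genes of amino acid uptake and synthesis had a median of 1.23 and the 9 endoplasmic reticulum genes one of 0.53. The other genes of the list were in neither group. The difference of 0.70 lay inside the −1.03 to 0.91 of shuffled memberships, a range too wide with so few genes to decide the question. An effect of RHCG and a difference between the cultures, such as nutrient supply, both remain possible with 1 library per group.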
